A study of Mus musculus with 32 samples.

How the data were processed

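H3K27ac ChIP-seq peak lists of 2 of the 32 samples in the labels were used, 1 library of untreated NSD1-dTAG mESCs and 1 of EBs at day 6. Per the labels' protocols, cells were dissociated and fixed with formaldehyde, chromatin was sonicated and immunoprecipitated, and fragments were selected by size. The fly chromatin spike-in named there concerns the RNA polymerase II samples. The submitters' processing notes name bcl2fastq 2.20.0.422, Bowtie2 2.3.4.1, SAMtools 1.9, MACS2 2.2.6 and deepTools 3.2.1, and the builds GRCm38.p6, mm10 and dm6, without roles. Peak names in the deposited lists carry the caller's name and a q-value threshold of 0.05. Whether a control library or pooled replicates entered the peak call is not given in the sources used here.

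Each list holds, for every peak, values the authors deposited as the caller wrote them: a fold ratio of the summit over the caller's background, the −log10 of its p-value and of its q-value, and a score that is 10 times the −log10 q without decimals, which was not used. The summit offset gives the summit's position. None of these values is scaled between libraries, so fold and −log10 q were used within a list to describe, rank and filter peaks. The closing observations set folds of a list against the lowest fold listed on background in the other, only to test explanations under which folds would be alike. Broad marked regions split by the caller count as several peaks, and a library with less coverage or enrichment yields fewer and narrower peaks, so the number of peaks reflects the library as well as the cells.

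The lists give no read totals. Since the caller's fold is (fragments + 1) / (background + 1), folds on the library-wide background are whole multiples of 1 step, and 67.2% of mESC peaks and 74.4% of EB peaks lay on that grid. On those peaks the recovered fragments gave back the deposited −log10 p within 0.000103, although near agreement with it was part of the grid's definition. For the other peaks the local background was fitted to the p-value, so they were not checked in this way. The background was 5.01 fragments in mESCs and 4.05 in EBs, and the median summit held 26 and 24 fragments. The shortest peaks were 300 and 259 bp.

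Gene coordinates came from the RefSeq gene table of GRCm38.p6 (49943 genes, 21887 of them protein-coding), the build of the lists. The table holds neither strand nor exons, and no genome sequence was used. The planned promoter windows were therefore replaced by windows of 1 kb around both ends of each gene, and the planned motif search was not run. In 94.1% of genes with a peak in both lists, the strongest peaks of both overlapped. Genes over 20000 bp long had peaks at both ends in 8.17% of mESC and 1.15% of EB cases. A peak can be counted for several genes: another gene's end lay within 1 kb of it for 29.4% of mESC-only genes, 39.4% of genes with both and 17.9% of EB-only genes. Exon, intron and UTR positions could not be given.

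Overlap meant at least 1 bp. Gene lists (22 lists, 333 genes, all matched to the table), the rule for named genes and the processing alternatives were fixed before the data were examined. For each list, the share of members with a mESC peak that had an EB peak, and the share of members without one that had an EB peak, were set against 10000 random lists of protein-coding genes of the same size, the former matched on the 10 strata of mESC fold. Random lists for the latter share were drawn without matching from all protein-coding genes that lack a mESC peak. Ties counted as 0.5 in percentiles. Random lists used protein-coding members only, while the counts include the noncoding imprinted genes. Percentiles describe these 2 libraries and are not p-values. For distal peaks within 50 kb of a gene end, random lists were matched on the number of such peaks. Here percentiles count a peak once for each member near it, noncoding members included, while the peak numbers given count it once. Distal peaks within 12.5 kb were joined, and clusters were ranked by the sum of fold times width.

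Named genes were 16 chosen in advance, up to 2 mESC-only and 2 EB-only members of each list with the highest fold, the 5 strongest distal peaks and the 5 top clusters of each condition, and the 10 EB-only genes with the highest fold. Klf2, Tbx3, Zic2, Zic5, Trim71, Sall4, Nsd3, Hdac1, Mixl1, Evx1, Nodal, Zeb1, Fn1, Dusp6, Spry2, Kcnq1ot1, Krt10 and Pomc fall outside this rule and were chosen after their values were seen, as were the gene families and extra lists of the closing observations. The values of 1 gene that the rule names are not reported here. The symbol pattern of the histone family was set after a first pattern had matched no gene. Alternatives were stricter q or fold thresholds, equal list lengths, other overlap rules, merged peaks, autosomes, other windows, other stitching, and ranks by −log10 q. Counting of peaks over the whole gene span, and removal of peaks whose local background exceeded 5 times that of the library, were added after seeing the data, as were lists without the member that has the most EB distal peaks and the immediate early list without 3 members.

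The steps were tested on simulated data. The overlap step found 5000 of 5000 planted overlaps, the gene-end step 200 of 200 planted genes and 0 others among 21887 genes, and the background was recovered as 4.50 where 4.5 had been planted. The planted gene-end peaks lay out of reach of other genes' ends, so the 0 others does not describe genes that share a peak. Of 100 simulated lists of 15 genes with no effect, whose median percentile was 59.0, 4 fell below percentile 2.5, and 95 of 100 lists that kept peaks at 25% of the usual chance did. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.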

Results

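Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in E14 mouse embryonic stem cells (mESCs). E14 is an established mouse line. In these cells the endogenous NSD1 protein, a histone H3 lysine 36 methyltransferase mutated in Sotos syndrome, carries a degradation tag (dTAG) through which the compound dTAG-13 removes it. The labels describe 32 samples in 24 groups, most of them RNA polymerase II and elongation factor profiles with or without dTAG-13. Peak lists of 2 samples were analysed here, both without dTAG-13 and both for H3K27ac. One came from mESCs kept in 2i/LIF, a medium with MEK and GSK3 inhibitors that holds cells in the naive pluripotent state. The other came from embryoid bodies (EBs) differentiated for 6 days in suspension in serum medium without these inhibitors. The other 30 samples, including the H3K27ac library of EBs given dTAG-13, were not analysed here, so no value below measures an effect of NSD1 loss. Each condition had 1 library and no replicates. The comparison therefore describes these 2 libraries and carries no test between conditions. Intervals are exact 95% Clopper-Pearson intervals and cover counting error only.

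The mESC list held 30897 peaks over 49.2 Mb and the EB list 8397 peaks over 5.91 Mb. The median peak was 938 bp wide in mESCs (quartiles 520 and 1876 bp) and 534 bp in EBs (362 and 847 bp). Fold enrichment at the summit, the authors' value for each peak, had a median of 4.32 in the mESC list and 4.91 in the EB list. These folds describe and rank peaks within a list, and the folds of a gene in both lists, where given side by side, do not measure a change. The library-wide background recovered from folds and p-values was 5.01 fragments per position in mESCs and 4.05 in EBs. A peak on that background needed at least 13 fragments at its summit in either library, a fold of 2.33 in mESCs and of 2.77 in EBs. A site without a listed peak was below the threshold of the peak call, which does not show that the mark was absent.

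The first question was how much of the mESC acetylation landscape was still listed in day 6 EBs. An EB peak overlapped 5823 of the 30897 mESC peaks, 18.8% (interval 18.4 to 19.3%). In the other direction, a mESC peak overlapped 6546 of the 8397 EB peaks, 78.0% (77.1 to 78.8%), and 1851 EB peaks had no mESC counterpart. Random placement of the EB peaks within their chromosomes gave 0.785% and 2.83%, the means of 100 placements. The shares depended on list length: against as many of the most significant mESC peaks as the EB list holds, they were 44.1% and 51.9%, and the gene-end share of mESC peaks described next was 43.4%. Requiring that the overlap cover at least 50% of both peaks lowered them to 7.30% and 26.9%.

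Peaks shared by both conditions lay mostly at gene ends, and those listed in mESCs alone mostly at a distance from gene ends. The annotation used here gives no strand, so a gene-end peak is one within 1 kb of either annotated end of a protein-coding gene, and a distal peak has no end of any annotated gene within 2.5 kb. Gene-end peaks made up 26.6% of the mESC list (26.1 to 27.1%) and 59.7% of the EB list (58.6 to 60.8%), while such windows cover 2.91% of the genome. Distal peaks made up 57.6% (57.0 to 58.1%) and 28.1% (27.2 to 29.1%). Of 8218 mESC gene-end peaks, 50.0% (48.9 to 51.1%) were overlapped by an EB peak. Of 17789 mESC distal peaks, 6.43% (6.07 to 6.80%) were. The 1851 peaks listed in EBs alone were distal in 52.6% and at gene ends in 33.2%.

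Strong mESC distal peaks were also mostly unmatched. Among the 10% of mESC peaks with the highest fold, an EB peak overlapped 1227 of 1479 gene-end peaks, 83.0% (80.9 to 84.8%), but 226 of 1135 distal peaks, 19.9% (17.6 to 22.4%). In the weakest 10% the shares were 10.4% and 1.63%.

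**Figure D1:**
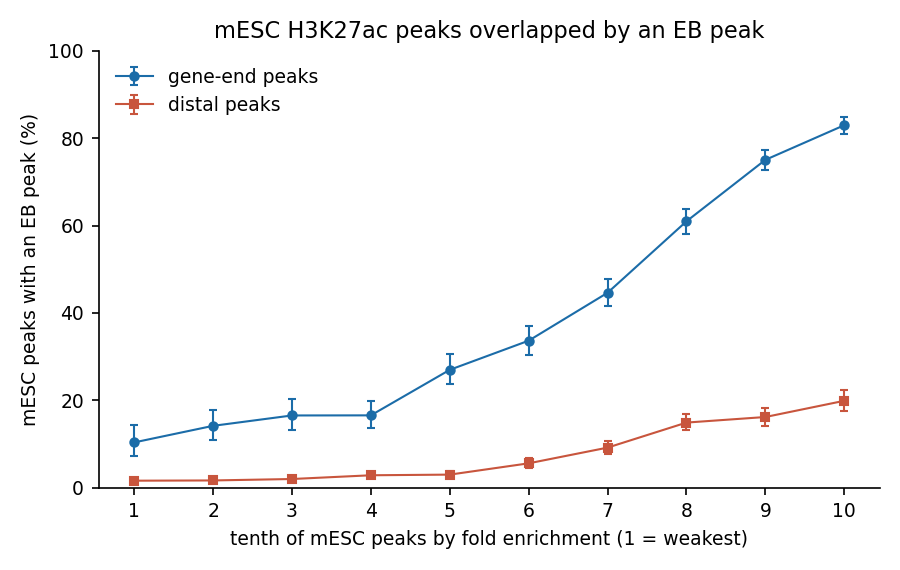
Share of mESC H3K27ac peaks overlapped by an EB peak (percent, vertical axis) in each 10% of mESC peaks ranked by fold enrichment (horizontal axis, weakest on the left), for gene-end peaks (circles) and distal peaks (squares); bars are exact 95% Clopper-Pearson intervals for 1 library per condition. The share rises with fold from 10.4 to 83.0% for gene-end peaks and from 1.63 to 19.9% for distal peaks.

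Most genes of the naive pluripotent state had a listed peak in mESCs and none in EBs, which is called a lost peak here. Across 21887 protein-coding genes, 4841 had a gene-end peak in both lists, 3404 in mESCs only, 526 in EBs only and 13116 in neither. Of the 8245 genes with a mESC gene-end peak, 58.7% (57.6 to 59.8%) had one in EBs too. The numbers of genes marked in 1 condition alone depend on list length: with as many mESC peaks as EB peaks, 1037 genes were mESC-only and 2046 EB-only. Among naive pluripotency factors, only 2 of the 15 members with a mESC peak had an EB peak, 13.3% (1.66 to 40.5%). Random lists of the same size matched on mESC fold kept a median of 73.3%, and the naive list lay at percentile 0 of 10000 of them. Lost members included Zfp42 (Rex1), a naive-state marker with a mESC fold of 35.9 at chromosome 8, 43307373 to 43311693, and Tfcp2l1, a factor acting downstream of LIF, at 29.5. Klf4, a factor used in reprogramming, had a mESC fold of 7.15 and no EB peak. Klf2 kept a peak, and the EB peak of Tbx3 lay at the other end of the gene from its strongest mESC peak. Esrrb, an orphan nuclear receptor of the naive network, had 6 mESC peaks and no EB peak within its span, none of them within 1 kb of an annotated end.

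Of the genes of pluripotency in general, some kept a peak and others lost it. Of the 14 members of that list with a mESC peak, 7 had an EB peak, 50.0% (23.0 to 77.0%, random median 71.4%, percentile 2.62). The share was 38.5% at a −log10 q of at least 5 and 15.4% at a −log10 q of at least 10, and it ran from 30.8 to 57.1% under the other alternatives. L1td1, with a mESC fold of 17.0, had none. At Pou5f1, which encodes OCT4, the mESC peak spanned 13660 bp with a fold of 34.9 and 209 fragments at its summit, and the EB peak spanned 300 bp with a fold of 3.50 and 17 fragments. At Sox2 the mESC peak spanned 8030 bp with a fold of 27.1, and the EB peak 371 bp with a fold of 3.37. Nanog had a mESC fold of 24.6, and its EB peak, with a fold of 3.92, lay past the other end of the gene and did not overlap the mESC peak. These EB peaks were near the threshold, and none of the 3 genes kept one when a fold of at least 4 was required in both lists. Trim71 and Sall4 kept stronger EB peaks, with folds of 12.9 and 8.12. Over the 4841 genes with a peak in both lists, the 7 shared members had a median fold percentile of 98.6 within mESCs and of 21.8 within EBs. Housekeeping genes, ranked the same way, had medians of 95.7 and 82.1.

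Around Sox2, distal peaks were also listed in mESCs alone. Sox2 lies on chromosome 3 at 34649995 to 34652461 (GRCm38), inside the long noncoding gene Sox2ot. Within 150 kb of it 14 peaks were listed in mESCs and 1 in EBs. A mESC peak at 34754799 to 34767718, with a fold of 32.3, was singled out after its values were seen, and no EB peak overlapped it.

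**Figure D2:**
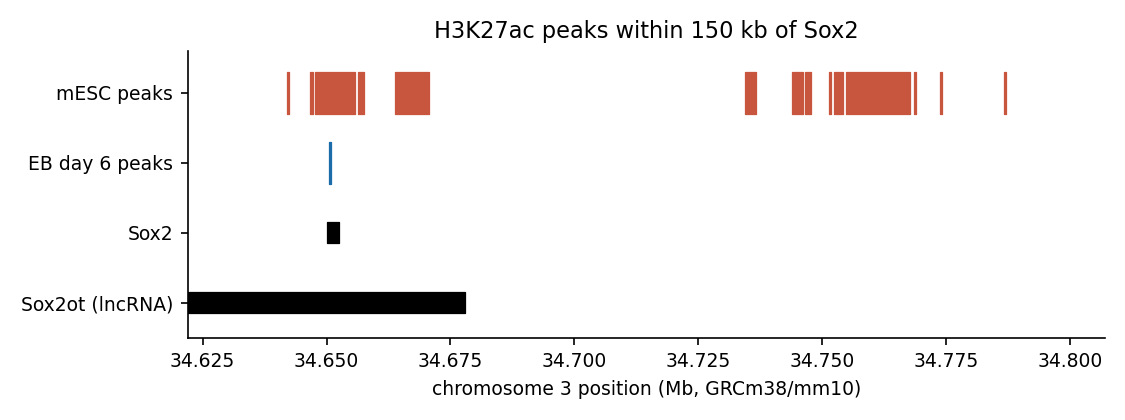
H3K27ac peaks within 150 kb of Sox2 on chromosome 3 (horizontal axis, Mb, GRCm38/mm10), with mESC peaks in the top row, EB peaks in the row under it and the annotated spans of Sox2 and Sox2ot at the bottom; bar lengths are to scale and heights carry no value. The 14 mESC peaks form groups at Sox2 and about 100 kb away, and the 1 EB peak lies at Sox2.

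Primitive streak genes had 5 EB-only members, the highest number among the 22 lists. Of 12 members without a mESC gene-end peak, 5 had one in EBs, 41.7% (15.2 to 72.3%), against a mean of 3.91% in random lists (percentile 100). The 5 were T (Brachyury), Mixl1, Evx1, Tbx6 and Snai1. The EB peaks of Mixl1 (fold 2.97, 14 fragments) and Evx1 (fold 3.57) were near the threshold and were not kept at a fold of at least 4. The random lists were drawn without matching from all 13642 protein-coding genes that lack a mESC peak. These include 1108 olfactory receptor genes, of which 0 had an EB peak, so the percentile does not compare streak genes with other developmental regulators. The T peak, at chromosome 17, 8433006 to 8433797, had a fold of 4.16, and an overlapping uncharacterised gene shares it. Snai1, a regulator of epithelial to mesenchymal transition, had the highest fold at 7.53, and Tbx6 had 4.36. At a −log10 q of at least 10, Snai1 alone was left with an EB-only peak (7.69%). Eomes, a T-box factor of the streak, had a peak in both lists, with folds of 2.49 in mESCs and 4.56 in EBs, and was EB-only at a −log10 q of at least 5 and at equal list lengths. Nodal also kept a peak, with an EB fold of 3.57, and Fgf17, with a mESC fold of 10.1, did not. The share of streak genes that kept a peak was 0% at a −log10 q of at least 5 and at a fold of at least 4.

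Later lineages showed few gene-end peaks in EBs. No member of the endoderm transcription factor, hemato-endothelial, neuroectoderm, Hox, trophectoderm or germline lists had an EB gene-end peak. In the share gaining one, these lists lay between percentile 11.7 (Hox) and percentile 36.5 (trophectoderm) of random lists, so that a count of 0 is not unusual for lists of their size. Gata4, Gata6, Sox17, Foxa2, Hand1, Kdr and Pax6, regulators of endoderm, mesoderm, endothelium and eye or brain, had a gene-end peak in neither list. EB distal peaks without a mESC counterpart lay within 50 kb of Kdr (2), Hand1 (2) and Gata6 (1). Within these lists mESC-only peaks were found at Foxa3 (4.16), at Klf1 (7.65) and Pecam1 (3.56), at Hoxc12 (4.49) and Hoxc13 (3.99), at Gata3 (9.65) and Tead4 (6.49), and at Hormad1 (3.27), the values being mESC folds. Gata3 held an EB peak within its span, and its class changed under 1 of the 7 settings run for gene lists. Among visceral endoderm products, Apoe alone had a gene-end peak, in mESCs, with a fold of 11.3. An EB peak lay within the Apoe span, and its class changed under 2 of the 7 settings run for gene lists. Basement membrane genes kept 0 of 4 mESC peaks (percentile 0.58), with Sparc at 10.6 and Lamc1 at 8.32, while Lamb1 had an EB-only peak with a fold of 4.95. Of the mesoderm and cardiac list, Bmp4 had a mESC-only peak (4.82) and Tbx3 alone had peaks in both. In the mesenchyme list Snai1 and Zeb2 (EB fold 5.55) had EB-only peaks, Vim (5.48), Prrx2 (4.49) and Zeb1 had mESC-only ones, and the fibronectin gene Fn1 had both.

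Formative genes were largely without gene-end peaks in either list. Otx2, a factor of the exit from the naive state, had a mESC fold of 9.48 and an EB fold of 3.57, at opposite ends of the gene, and Cdh2, which encodes N-cadherin, had an EB-only peak with a fold of 5.55. Zic2 and Zic5, zinc finger genes, had overlapping peaks in both lists. The other 8 of 12 members had a gene-end peak in neither list. Within 50 kb of the ends of the 12 genes, 19 distal peaks were listed in mESCs and 6 in EBs. That EB share lay at percentile 93.5, and at percentile 75.2 with equal list lengths. Near Fgf5 lay 2 EB distal peaks without a mESC counterpart.

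Targets of FGF and ERK signalling were mostly marked in both conditions. Of 9 members with a mESC peak, 7 had an EB peak, 77.8% (40.0 to 97.2%, percentile 74.6), among them the feedback inhibitors Dusp6 and Spry2 with EB folds of 11.9 and 13.7. Of the 3 without a mESC peak, Fos and Egr1, immediate early transcription factors, had EB peaks with folds of 12.9 and 9.31. That is a share of 66.7% (9.43 to 99.2%, percentile 99.8 of unmatched random lists). Etv4 (16.3) and Ier3 (3.73) had mESC-only peaks. Among WNT targets, Lef1 (6.93) and Znrf3 (3.17) had EB-only peaks, and Notum (16.4) and Cdx1 (6.49) mESC-only ones. Of the WNT, BMP and Nodal targets with a mESC peak, 2 of 5, 3 of 3 and 3 of 5 kept one. The strongest peaks overlapped in 1 of the 2 WNT targets. In the same order, the shares were 20.0%, 66.7% and 20.0% at a −log10 q of at least 5. They were 0%, 33.3% and 0% at a −log10 q of at least 10, and 50.0%, 100% and 100% at equal list lengths. For BMP and Nodal targets the EB-only genes were Id1 (8.12) and Skil (8.52), and Lefty1 (4.16) and Lefty2 (3.66) had mESC-only peaks. A higher share of members without a mESC peak gained an EB one than in the mean random list for all 4 pathways, but each rests on 1 or 2 genes.

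Most housekeeping genes and chromatin regulators had a peak in both lists. All 15 housekeeping genes with a mESC peak had an overlapping EB peak (78.2 to 100%, percentile 98.7), and B2m had an EB-only one (3.57). Of 10 genes for H3K36 methyltransferases, acetyltransferases and deacetylases with a mESC peak, 9 had an EB peak, 90.0% (55.5 to 99.7%, percentile 95.9), although those of Nsd3 and Hdac1 lay at opposite gene ends in the 2 lists. Nsd1 itself, on chromosome 13 at 55209782 to 55318325, had overlapping peaks at its lower end, with a fold of 15.6 in mESCs and of 9.31 in EBs. The exception was Kat2b, which encodes the acetyltransferase PCAF and had a mESC peak of 29244 bp with a fold of 25.8. Of the imprinted genes, Peg3 and Usp29, whose facing ends share 1 peak, had it in mESCs only (7.98). Peg10 and Sgce, which also share 1 peak, had it in EBs only (4.76). EB peaks lay within the spans of Peg3 (1) and Usp29 (4), and mESC peaks within that of Sgce (2). The classes of Peg3, Usp29 and Sgce changed under 3 of the 7 settings run for gene lists, and that of Peg10 under 1. The noncoding Kcnq1ot1 was the 1 of 4 imprinted genes that kept a mESC peak. The share kept was 57.1% with windows of 2.5 kb and 0% at a −log10 q of at least 10. Among adult tissue genes, included as a control list, Krt10 and Pomc had peaks in both lists and Scgb1a1 in mESCs only (9.60). This list kept 0% of its mESC peaks at a −log10 q of at least 5 and at a fold of at least 4.

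**Figure D3:**
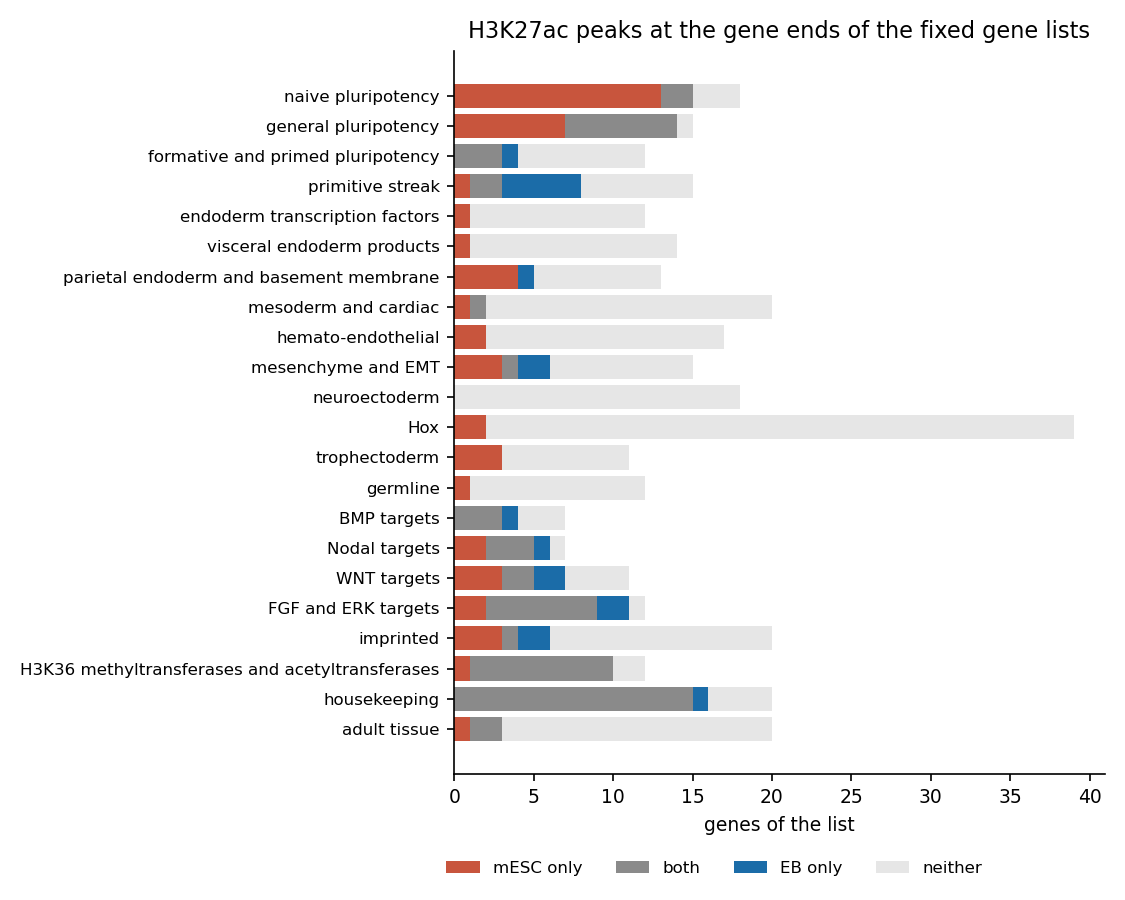
Number of genes (horizontal axis, bars from 0) in each of the 22 fixed gene lists (vertical axis) with an H3K27ac gene-end peak in mESCs only, in both lists, in EBs only or in neither, from 1 library per condition. Of the naive pluripotency genes 13 fall in the mESC-only class, and 5 primitive streak genes fall in the EB-only class.

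Over all genes, the 10 EB-only genes of highest fold included the immediate early genes Fos (12.9) and Fosb (11.5). Next to these were the lipid enzyme gene Dgat2 (13.7), Tcf12 and Zmynd11 (12.5 each), and 1700029J07Rik and Ufsp2, which share 1 peak (12.4). The rest were Lrrc74b, Nuak1 and P2rx6 (11.5 each), of which Lrrc74b and P2rx6 share 1 peak. EB-only refers to gene ends, and mESC peaks lay within the spans of Tcf12 (2), Nuak1 (2), Zmynd11 (1) and Lrrc74b (1). The other genes named here had 0. The class of Zmynd11 changed under 3 of the settings run for gene lists. Those of Tcf12, Nuak1, Lrrc74b and Fosb changed under 1 each.

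Distal peaks around the lists followed the gene-end pattern for naive genes. Within 50 kb of their ends, naive pluripotency genes had 78 distal peaks in mESCs and 3 in EBs, an EB share of 3.70% (0.770 to 10.4%, random median 10.8%, percentile 2.35). Over all distal peaks the EB share was 11.7%. With as many mESC peaks as EB peaks the shares were 10.7% near naive genes and 40.2% over all distal peaks. General pluripotency genes, at 70 and 9 peaks, lay at percentile 49.5. Higher EB shares were found around mesenchyme genes (20 mESC and 11 EB peaks, percentile 99.7), FGF and ERK targets (31 and 12, percentile 99.1) and imprinted genes (19 and 10, percentile 99.96). The imprinted percentile counts an EB peak again for each neighbouring member and includes noncoding H19 and Meg3. It therefore belongs to a higher EB share than the 34.5% that 19 and 10 peaks give. Snai1 alone accounted for 5 of the 11 EB peaks near mesenchyme genes, and without it the share fell from 35.5% to 24.0% (percentile 92.4). Without Fos, FGF and ERK targets lay at percentile 94.9. At equal list lengths the mesenchyme, FGF and ERK, and imprinted lists lay at percentiles 98.8, 90.7 and 94.8. These lists without 1 member were examined after the values were seen. Around basement membrane genes 33 distal peaks were listed in mESCs, 16 of them near Lamc1, and 0 in EBs (percentile 4.58). With equal list lengths the numbers were 4 and 0 (percentile 9.89).

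Among distal peaks listed in mESCs alone, the highest fold, 37.5, was at chromosome 15, 7113617 to 7121648, inside Lifr, the LIF receptor gene. Next came a peak 62.0 kb from Fam53a (37.3), one inside Manba (36.1), one inside Esrrb at chromosome 12, 86492166 to 86513075 (33.9), and one 13.9 kb from Smarcad1 (33.4). The strongest EB-only distal peaks, with 51 to 83 fragments at the summit, lay 11.6 kb from Zswim4 (fold 16.6), inside Sema4c (16.2), inside Maml3 (10.7), 33.8 kb from Mfap3l (10.3), and 8.10 kb from Id3 (10.3), a BMP target, at chromosome 4, 136134276 to 136135724.

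Joined into clusters, distal peaks gave 10262 mESC clusters and 1943 EB clusters. Of the top 200 mESC clusters, 13 overlapped one of the top 200 EB clusters, 6.50% (3.51 to 10.9%). Any EB distal peak lay in 65 of these 200 mESC clusters, and a mESC distal peak in 130 of the top 200 EB clusters. The leading mESC clusters overlapped Etl4, Esrrb, Tns3, Rpl7l1 with Bicral, and Smarcad1; the Esrrb cluster held 5 peaks over 59.1 kb on chromosome 12 and no EB peak. In EBs the leading cluster was a single peak of 12285 bp on chromosome Y, 28258 bp from the predicted gene Gm52481. It was followed by clusters at Tmem267, near Chd2, at Rpl19 and near Zswim4. All 5 of these EB clusters contained a mESC peak.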

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

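Counting over whole gene spans and leaving out peaks on high local background were chosen after seeing the data, as were lists without 1 or 3 members. No paired analysis was possible because each condition had 1 library and the results come from no test. Leaving out replicates was not possible either, and the planned motif search was not run. At a −log10 q of at least 10, mESC peaks numbered 13827 and EB peaks 3505, overlap shares were 20.2% of mESC and 83.7% of EB peaks, gene-end shares 38.6% and 76.0%, and genes with both peaks 2794, with EB peaks only 343. The share of genes that kept a peak was then 45.8%, that of naive genes 0%, that of primitive streak genes gained 7.69%, and the EB share of distal peaks near naive genes 0%. At a −log10 q of at least 5, overlap shares were 20.1% and 81.1%, gene-end shares 32.02% and 68.5%, and 54.5% of genes kept a peak. With mESC peaks reduced to the EB number, overlap shares were 44.1% and 51.9%, the mESC gene-end share 43.4%, mESC-only genes 1037, EB-only genes 2046, genes keeping a peak 76.2%, and the EB share of distal peaks near naive genes 10.7%. At a fold of at least 4, the mESC overlap share was 24.8% and gene-end shares 36.1% and 69.0%. Overlap of 50% of both peaks gave 7.30% and 26.9%, summits inside the other peak 16.3% and 76.6%, and merging peaks within 500 bp 21.1% of mESC peaks. Windows of 500 bp gave gene-end shares of 24.3% and 55.1% and 57.5% of genes keeping a peak; windows of 2.5 kb gave 32.5% and 64.99%. With whole gene spans 57.5% kept a peak. The top 500 clusters overlapped in 11.4%. Fewer or wider items follow from these settings by construction, and no other cause was tested. Under the 7 settings run for gene lists, naive genes kept at most 16.7% of their peaks and housekeeping genes at least 93.3%. Leaving out peaks on high local background moved neither overlap share nor the cluster share, for which alone it was run, beyond its interval. The classes of Eomes, Hormad1, Otx2, Sox2 and Znrf3 changed under 4 of 7 settings. Of 476 class calls of named genes under alternatives, 84 changed. None went from mESC-only to EB-only or back, but none could, because each setting either only removed or only added peaks.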

Other observations

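The gene families, the immediate early and heat shock lists, and all tests of explanations in this part were chosen after the main results were seen. Of 25 gene families defined by symbol, cytosolic ribosomal proteins kept 73 of 80 mESC gene-end peaks in EBs, 91.2% (82.8 to 96.4%, percentile 99.97 of matched random lists), and E2 ubiquitin-conjugating enzymes kept 20 of 22 (percentile 99.02). Solute carriers, the membrane transporters, kept 58 of 139, 41.7% (33.4 to 50.4%, random median 54.0%, percentile 0.070). Zinc finger genes kept 133 of 254 (percentile 10.9), and 17 of the 143 without a mESC peak had one in EBs, 11.9% (7.08 to 18.4%), against a mean of 3.77% in random lists (percentile 99.98). As for primitive streak genes, the random lists for this last share were unmatched and could hold olfactory receptor genes, which had no EB peak. Heat shock genes kept 9 of 10 (percentile 93.7), although the strongest peaks of Hspa5 in the 2 lists did not overlap. Replication-dependent histone genes kept 61 of 62, but these rest on 24 distinct mESC peaks. The 21 protocadherin genes that lost a peak share 1 mESC peak at a common gene end and count as a single observation.

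Peaks on a local background over 5 times that of the library numbered 99 in mESCs and 36 in EBs, and 31 of those in EBs overlapped a mESC peak.

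The first pattern is that the EB list was shorter and its losses were mainly distal. Lower coverage of the EB library as the whole cause is argued against by 6261 unmatched mESC peaks, 24.97% of all unmatched ones, with a fold over 2 times the lowest EB fold on background, and thinning mESC fragments to the EB background left 28796 peaks. Weaker enrichment in the EB library as the only difference is argued against by the EB-only peaks, of which 30.04% had a fold over 2 times the lowest mESC one, and, for the gap between gene-end and distal peaks, by a difference of 37.2 percentage points at the same mESC fold and width (49.9% against 12.7%). Weaker enrichment as a contributor to the lower number stays open, since the lists hold no share of fragments in peaks, and so does a preference for GC-rich sites, which needs a genome sequence. Differentiation, including a mix of cell types in which enhancers of each type are diluted, was not tested.

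The second pattern is the loss of gene-end peaks at naive pluripotency genes. Lower coverage is argued against by 11 of the 13 lost members, whose mESC fold lay above 2 times the lowest EB fold on background. A general loss that any genes with peaks of the same fold would show is argued against by percentile 0 among matched random lists. That percentile is the value given in the results, not a further test, and the lists were matched on mESC fold alone. Solute carriers (percentile 0.070) and basement membrane genes (percentile 0.58) also lay low, so low retention was not limited to naive genes. With 1 library per condition, a difference between cultures stays open, and exit from the naive state during EB differentiation is a hypothesis that may account for the loss but was not tested.

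The third pattern is EB acetylation at immediate early genes, which respond within minutes to growth factors and stress. Of 22 such genes, 10 of the 11 with a mESC peak kept one (percentile 99.5). Among these 10, the strongest peaks of Zfp36 and of Btg2 in the 2 lists did not overlap. Of the other 11 genes, 5 had an EB-only peak, 45.5% (16.7 to 76.6%): Fos, Fosb, Egr1, Nr4a2 and Srf. The list was made after Fos, Fosb and Egr1 had been seen as EB-only, and without these 3 the count was 2 of 8 (percentile 98.1 of unmatched random lists). Of these 2, Nr4a2 and Srf, the Srf peak ended at 46557274 and the gene at 46558267. It thus only just reached the 1 kb window, and 1 mESC peak lay within the Srf span. A stress response during handling of the embryoid bodies could produce this, but only 2 heat shock genes lacked a mESC peak, and 0 of them had an EB peak. Absence of the MEK inhibitor of 2i medium could as well, but only 1 FGF and ERK target outside the immediate early genes lacked a mESC peak, and 0 had an EB peak there, so that with so few genes these explanations cannot be told apart.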
